A study of Taeniopygia guttata with 8 samples.

How the data were processed

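H3K27ac, the acetylation of histone H3 at lysine 27 that marks active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in adult male zebra finches. The tissue came from 2 song nuclei: RA, the robust nucleus of the arcopallium and a motor output of the song system, and Area X, a song nucleus of the striatum. Per the labels' protocols, brains were taken after 1 to 2 hours of silence or singing from 18 birds per behaviour. The singing samples are labelled as 2 hours of singing. The dissected nuclei were pooled from 6 birds, which gave 3 pools per behaviour. The sample source is labelled as laser-captured tissue, whereas the protocol describes dissection from 400 µm sections. Tissue was fixed for 15 min in 1% formaldehyde and sonicated to 200 to 400 bp. The antibody is listed with 2 lots, and which library used which lot is not given in the sources used here.

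The authors deposited one table of raw read counts with 35958 genomic regions and 14 libraries. Per the submitters' processing notes, SAMtools 1.1, bedtools, MACS2 2.1 and HTSeq 0.6.1 were used, with no role stated for each. The aligner, the genome build, the criteria by which regions were called, and the set of libraries in which they were called are not given in the sources used here. The smallest gap between neighbouring regions was 501 bp. Coordinates are printed as in the deposited table, with starts counted from 1.

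The deposited counts were assigned to groups from their column names, which carry the nucleus, the word minus or plus, and a number. Minus was read as silent and plus as singing. This is a reading of the names, and the direction of every comparison of behaviour rests on it. The names do not state the assay; the columns were taken as H3K27ac libraries. The series describes 4 H3K27ac samples and 4 whole-cell extracts, one of each per nucleus and behaviour. The whole-cell extracts were not analysed here, so counts were not compared with an input. The table has 3 silent and 4 singing libraries per nucleus, while the labels state 3 pools per behaviour. Where the fourth singing library came from is not stated in the sources used here. The numbered libraries were taken as separate pools. If some are repeat libraries of one pool, the p-values measure technical spread in part and are too small. The labels give birds and pools per behaviour and not per nucleus, so RA and Area X libraries may come from the same birds. The main model, the simulations and the permutations of libraries treated them as independent. In a chi-square comparison of counts over regions with at least 10 reads in a pair, the lowest value per degree of freedom was 1.32. It came from RA silent library 2 with RA singing library 4. The latter is the shallowest library, and all its pairs were low, at 1.32 to 5.06. Without it, the lowest was 3.13, for RA silent library 1 with RA singing library 1. That pair crosses behaviours and had a Spearman coefficient of 0.963. The comparison covers counting error only, and does not tell repeat libraries of one pool from separate pools. All 14 libraries were kept.

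Reads in regions summed to between 0.203 M and 10.6 M per library (M, 1e6 reads). These totals are reads within the listed regions and not the sequencing depth. RA singing library 4 had a median of 3 reads per region, and 17% of its regions had none.

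Counts were analysed in R 4.3.3 with edgeR 4.0.16. Regions were filtered with filterByExpr on the 4 groups, which removed 4 and left 35954. Libraries were scaled by TMM, and one model with a mean for each group was fitted to all 14 libraries with robust quasi-likelihood dispersions. The 7 contrasts were Area X against RA averaged over behaviour and within each behaviour, singing against silent within each nucleus and averaged over both, and the difference of the singing effect between nuclei. Contrasts were tested with glmQLFTest and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors were the absolute log2 fold change over the square root of F. Values per library are TMM-scaled CPM (counts scaled to 1e6 reads per library), given as mean ± SD. Regions are named by a rule fixed before the data were examined. It takes, for each contrast and direction, the 10 largest fold changes among regions past the threshold whose CPM did not overlap between sides and whose mean CPM was at or above the median. Where no region passed, it takes the 5 with the smallest p. Shares of reads were compared by exact two-sided permutation of the 7 Area X and 7 RA libraries.

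The count test was tested on simulated data with a common mean per region over all libraries, the fitted spread and 200 changed regions per contrast. Simulated counts were drawn independently for each region and library, without the variation that real regions share. For Area X against RA averaged over behaviour, it recovered 20% of 2-fold changes, 84% of 4-fold changes and all 50 of 8-fold changes. This was among 35939 simulated regions, with 8 false calls. In the real data 19316 regions were called for this contrast, and with that many the Benjamini-Hochberg threshold is easier to pass. These rates therefore do not tell what share of real differences between the nuclei was missed.

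Alternatives fixed before the data were examined were DESeq2 size factors, total-count scaling, the DESeq2 1.42.0 Wald test, no low-count filter, a stricter filter, a replicate block, a fit to the compared groups alone, stricter thresholds, and each library left out in turn. Further alternatives were added after seeing the data, among them limma 3.58.1 (voom) with library quality weights and surrogate variables. The surrogate variables were the leading components of the residuals of the group model, added to it as covariates. They shrink the residual spread by construction, so p-values from those fits may be too small. Since the build of the deposited coordinates is not given, the annotation at hand could not be matched to them. No region was therefore assigned to a gene, and the 14 gene lists planned for the comparisons were not tested.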

Results

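H3K27ac was measured by ChIP-seq in RA, the pallial motor nucleus of the song system, and in Area X, the striatal song nucleus, of adult male zebra finches that had been silent or had sung. The deposited counts cover 35958 genomic regions in 3 silent and 4 singing libraries of each nucleus. The group of each library was read from its column name, with minus taken as silent and plus as singing. Regions had a median width of 764 bp (quartiles 442 and 1450 bp) and covered 44.3 Mb, and 9.89% lay on unplaced or random sequence. The build of the coordinates is not given in the sources used here, so regions are named by position and not by gene.

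Reads in regions (M, 1e6 reads) numbered 5.41 M, 4.33 M and 9.48 M in the RA silent libraries 1 to 3. The RA singing libraries 1 to 4 held 4.88 M, 1.08 M, 3.03 M and 0.203 M. The Area X silent libraries held 4.64 M, 6.73 M and 10.6 M, and the Area X singing libraries 6.62 M, 6.42 M, 4.84 M and 8.28 M. The common biological coefficient of variation was 0.392. Area X libraries of one behaviour correlated with a median Spearman coefficient of 0.92 across regions, and RA libraries of one behaviour with 0.786. Pairs of different behaviour in the same nucleus were no less alike, with medians of 0.935 in Area X and 0.806 in RA. RA silent library 2 correlated better with Area X libraries (median 0.904) than with the other RA libraries (0.809), and its closest library was Area X silent library 1 (0.946). RA singing library 4 had medians of 0.791 to Area X and 0.691 to RA. On an axis set to 0 at the mean of the other RA libraries and 1 at the mean of the other Area X libraries, these 2 libraries lay at 0.57 and 0.67. The remaining RA libraries lay between -0.44 and 0.14, and the Area X libraries between 0.60 and 1.30.

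**Figure D1:**
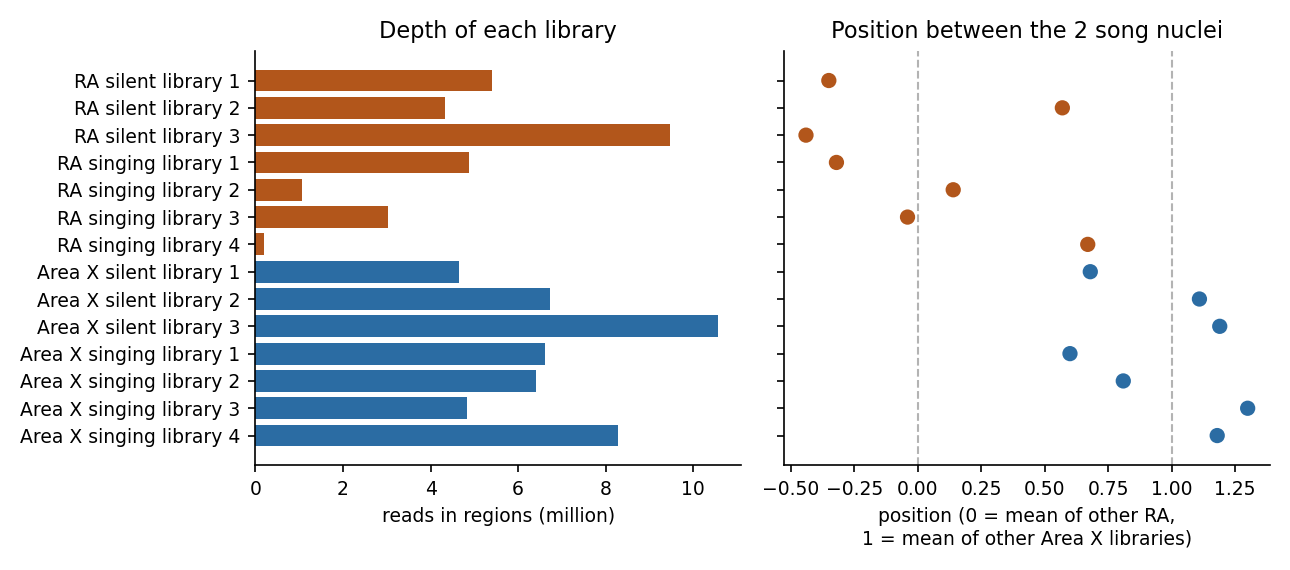
Reads in regions per library in M (left) and the position of each library between the RA and Area X means over regions called without it (right, no unit), with RA in orange and Area X in blue. RA silent library 2 at 0.57 and RA singing library 4 at 0.67 lie apart from the other RA libraries, and RA singing library 4 is the shallowest at 0.203 M reads.

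The first comparison addressed how H3K27ac differs between the 2 song nuclei. Of 35954 tested regions, 10233 were higher in Area X and 9083 higher in RA, together 53.7% (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). The median fold was 2.54 among regions higher in Area X and 2.31 among those higher in RA, and 7858 and 6640 of them exceeded 2-fold. The largest differences toward RA fell in 2 loci. All 10 regions named toward RA lay on chromosome 10 or on chromosome Z. At chrZ:14136487-14137869, CPM was 43.9 ± 16.7 in RA and 4.84 ± 2.50 in Area X (SD, n = 7 each), a 10.1-fold difference (log2 fold change -3.34, SE 0.32, edgeR adjusted p = 5.27e-05). At chr10:16297965-16300877, CPM was 56.8 ± 20.5 in RA and 6.45 ± 2.97 in Area X, a 9.39-fold difference. At chr10:16288688-16295073, the strongest of the 10 in RA, it was 167 ± 57.6 against 24.7 ± 11.4.

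The regions named toward Area X lay on 8 chromosomes. At chr20:4621828-4623402, CPM was 34.1 ± 8.82 in Area X and 6.13 ± 5.33 in RA (SD, n = 7 each), a 6.44-fold difference (log2 fold change 2.69, SE 0.47, edgeR adjusted p = 0.00101). At chr3:39461302-39462622, CPM was 121 ± 31.9 in Area X and 22.4 ± 22.2 in RA, 6.08-fold. RA silent library 2 stood at 69.8 CPM there, against 7.83 to 30.4 in the other RA libraries. At chr10:20228000-20229382 the difference was 5.53-fold, and at chr24:847534-850267 it was 5.23-fold. CPM did not overlap between the 7 Area X and 7 RA libraries in 1575 regions with higher values in Area X and 1319 with higher values in RA, of which 1571 and 1315 were called; chance gives such a separation, in either direction, in 0.0583% of regions.

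The balance of the 2 directions depended on the scaling and on the libraries. With total-count scaling, which moved the median log2 fold change of all regions from -0.04 to -0.35, 7045 regions were higher in Area X and 12301 higher in RA. Without RA silent library 2 and RA singing libraries 2 and 4, a choice made after seeing the data, 10960 and 11035 regions were called. Without the number 1 libraries of all 4 groups they were 7664 and 9321, and with 2 surrogate variables 11813 and 7077, both also chosen after seeing the data.

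Neighbouring regions differed together. The log2 fold changes of neighbours correlated with Pearson's r = 0.86 across 3867 pairs up to 1000 bp apart and with r = 0.17 across 2861 pairs over 100000 bp apart; regions are not independent replicates. Runs of at least 5 consecutive regions called in one direction, with gaps of at most 10000 bp, numbered 219 toward Area X and 164 toward RA. When calls were shuffled within chromosomes 1000 times, the medians were 8 and 10 and the highest 22 and 22 (permutation p = 0.001 for each, the smallest these shuffles can give). Shuffling treats neighbours as exchangeable, which regions this correlated are not. The p-values therefore restate that calls cluster and do not tell what made them cluster. The longest run toward RA was chr10:16255984-16314220, with 19 regions, where summed CPM was 724 ± 271 in RA and 151 ± 42.2 in Area X (SD, n = 7 each). The run chrZ:14098145-14151673 held 15 regions, with 824 ± 281 in RA and 162 ± 47.6 in Area X. Toward Area X, 3 runs held 17 regions. They were chr2:89529493-89607200 (1570 ± 597 in Area X, 466 ± 346 in RA), chr4:61637644-61730172 (1410 ± 555 and 441 ± 283) and chr20:4609529-4669436 (563 ± 129 and 211 ± 99.6). In the chromosome 2 and chromosome 4 runs, RA silent library 2 (916 and 823) and RA singing library 4 (913 and 808) lay within the range of the Area X libraries, from 857 and 744 upward. RA silent libraries 1 and 3 and RA singing library 1 lay between 145 and 209 in both.

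**Figure D2:**
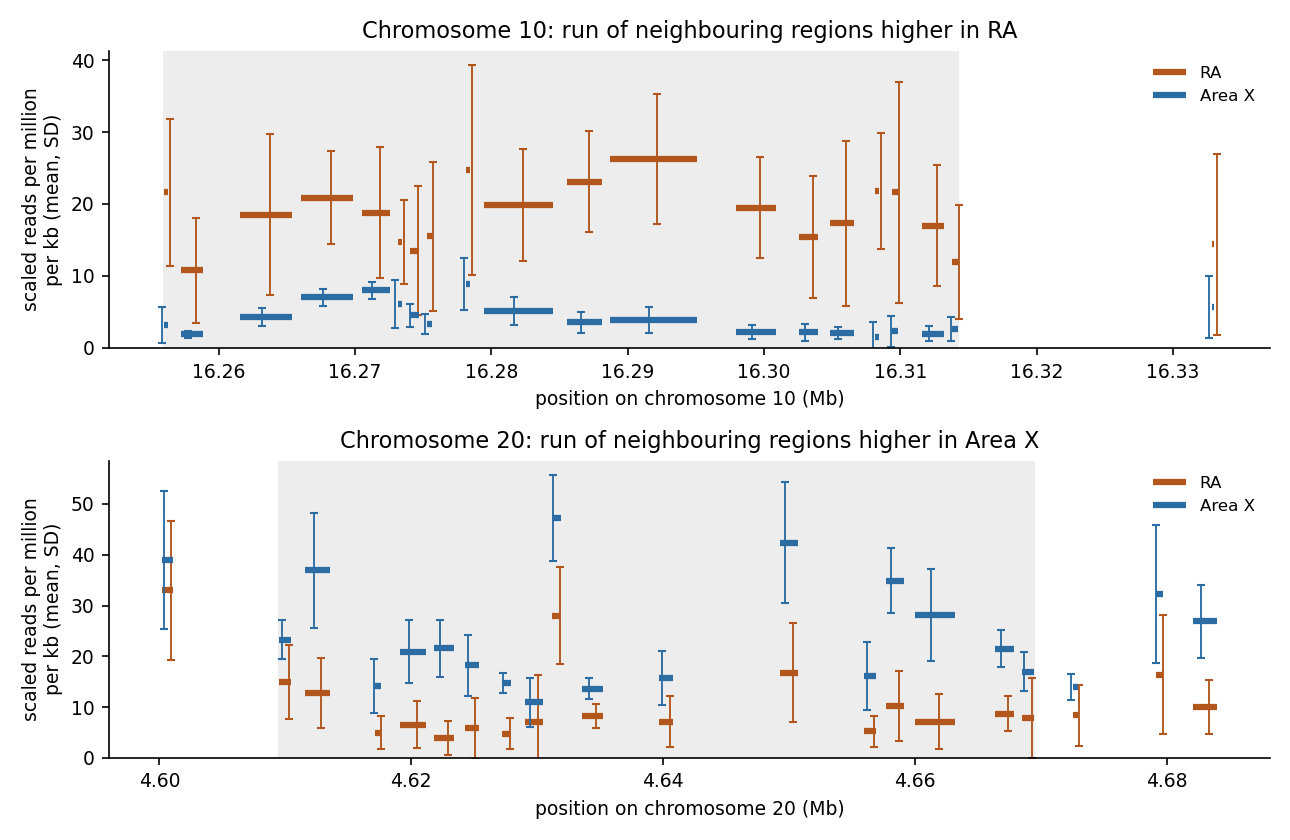
TMM-scaled CPM per kb of each region (bars, mean of 7 libraries; whiskers, SD, drawn from 0 where it would fall below) against position in Mb on chromosome 10 and chromosome 20, with RA in orange and Area X in blue. The grey run on chromosome 10 holds 19 regions higher in RA and the grey run on chromosome 20 holds 17 regions higher in Area X.

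Under TMM scaling, direction went with the width of the regions and with their mean signal. Among the 7190 regions with the lowest mean signal, 16.6% were higher in Area X and 32.7% in RA. Among the 7191 with the highest, these shares were 47.8% and 14.5%. Among 1549 regions over 4000 bp, 62.2% were higher in Area X and 20.4% in RA, whereas among 11028 regions up to 500 bp these shares were 17.5% and 25.4%. Regions over 4000 bp held 29% ± 2.4 of the reads in Area X libraries and 24% ± 2.8 in RA libraries (SD, n = 7 each, exact two-sided permutation p = 0.00408, adjusted p = 0.0163 over 8 classes). With signal-dependent scaling, chosen after seeing the data, the shares in regions over 4000 bp were 38.6% and 33%, and in regions up to 500 bp they turned to 20.5% in Area X and 16.5% in RA, so the excess toward Area X in wide regions was smaller under that scaling and the excess toward RA in narrow regions was lost. Total reads in regions were 48.1 M over the Area X libraries and 28.4 M over the RA libraries.

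**Figure D3:**
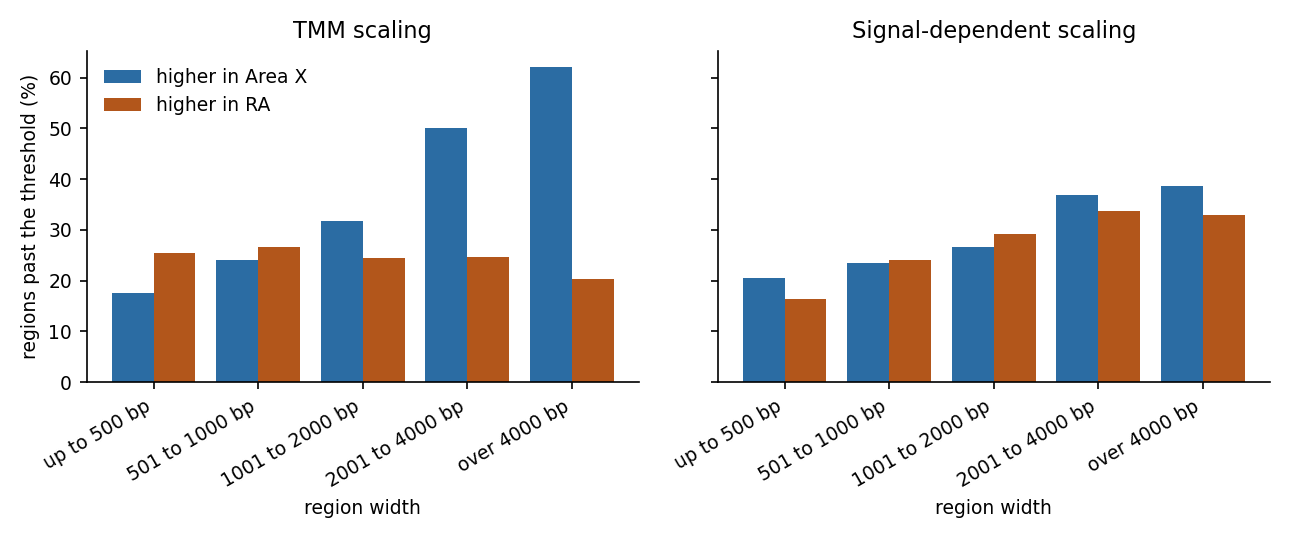
Percent of regions past the threshold toward Area X (blue) and toward RA (orange) by region width, with TMM scaling (left) and with signal-dependent scaling (right). Under TMM, 62.2% of regions over 4000 bp were higher in Area X and 20.4% in RA; under signal-dependent scaling, 38.6% and 33%.

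The share of reads per chromosome also differed, in 14 of 33 chromosome classes after adjustment. Chromosomes 1, 1A, 2 to 5 and Z together took 38.6% ± 1.4 of the reads in RA and 41% ± 1.7 in Area X (SD, n = 7 each, exact permutation p = 0.0186, adjusted p = 0.0213). The other placed chromosomes took 54.8% ± 1.4 and 52.4% ± 1.4 (exact permutation p = 0.00816, adjusted p = 0.0163). Chromosome 11 took 2.88% ± 0.28 of the reads in RA and 2.27% ± 0.17 in Area X (SD, n = 7 each, exact permutation p = 0.00117, adjusted p = 0.0116), and 297 of its 737 regions were higher in RA against 95 in Area X. Chromosome 1 took 6.15% ± 0.36 in RA and 6.97% ± 0.37 in Area X (exact permutation p = 0.0035, adjusted p = 0.0128), with 467 of 2612 regions higher in RA and 965 higher in Area X. Chromosomes 11 and 1 followed the split above, and their shifts were not shown to be particular to them. Chromosome 13 went against it, with 3.2% in RA and 3.44% in Area X. So did chromosome Z, which was summed with chromosomes 1, 1A and 2 to 5. It took 3.75% in RA and 3.48% in Area X (exact permutation p = 0.0233, adjusted p = 0.0513). Chromosome 4A and some others with smaller shifts also went against it. Base composition of the regions was not examined.

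The nuclei were then compared within each behaviour. The chromosome Z and chromosome 10 loci were higher in RA in both behaviours. At chrZ:14136487-14137869 the fold toward RA was 15.2 in silent birds (edgeR adjusted p = 0.00315) and 6.75 in singing birds (adjusted p = 0.0203). At chr10:16297965-16300877 it was 12.4 and 7.10. At chr20:4621828-4623402 the fold toward Area X was 5.48 in silent birds and 7.56 in singing birds. At chr1:79084329-79087208, the largest fold toward Area X named in silent birds, it was 6.27, and at chr3:39571507-39572858, the largest named in singing birds, it was 8.82. In silent birds, 3721 regions were higher in Area X and 3414 higher in RA (3 libraries each). In singing birds, 3728 were higher in Area X and 2907 in RA (4 libraries each). These comparisons share no library, but they share the regions and the estimate of the spread. Deviations of the number 1 libraries also correlated between behaviours, at 0.57 in RA and 0.58 in Area X. The lists had 2022 calls toward Area X in common, against 386 for independent lists, and 1856 toward RA, against 276. Because the lists are not independent, 386 and 276 are too low as expectations. No region was called in opposite directions. Fold changes correlated across regions with Pearson's r = 0.89 and Spearman's rho = 0.91.

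Both counts depended on the threshold, on the groups in the fit and on single libraries. At an adjusted p under 0.01 in edgeR, 8 regions were called in silent birds and 0 in singing birds, where 15774 and 14291 had an unadjusted p under 0.05. With the compared groups alone in the fit, edgeR called 0 in silent birds, with 15180 at an unadjusted p under 0.05, and 6058 in singing birds. In silent birds, of 7135 called, 0 were called without Area X silent library 2 or 3, 10 and 3 without RA silent library 1 or 3, 14521 without RA silent library 2, and 11042 without Area X silent library 1. The singing libraries, which share the estimate of the spread, moved it to 4135 without RA singing library 3 and to 3593 and 3963 without Area X singing library 2 or 4. In singing birds, of 6635 called, 0 were called without RA singing library 3 or Area X singing library 3 or 4, and 1986, 2847 and 2872 without RA singing library 1 or 2 or Area X singing library 2. Toward Area X and RA, the last 3 were 428 and 1558, 981 and 1866, and 1925 and 947. With total-count scaling, calls toward Area X and RA numbered 1911 and 4815 in silent birds and 1555 and 5579 in singing birds. With DESeq2 size factors in edgeR, they were 1679 and 2401 in silent birds. With signal-dependent and with width-dependent scaling, both chosen after seeing the data, they were 2769 and 3257, and 3161 and 3653, in silent birds, and 2122 and 3019, and 2593 and 3492, in singing birds. Among regions at or above the median CPM, they were 1302 and 2618 in silent birds and 1461 and 2475 in singing birds. Without the number 1 libraries they were 2075 and 4394 in silent birds and 1919 and 2924 in singing birds, and with 2 surrogate variables 7857 and 2356 in singing birds.

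The comparison of behaviours addressed whether H3K27ac differed between singing and silent birds. No region passed the test in RA or in Area X, in the mean of both nuclei, or for the difference of the singing effect between nuclei (edgeR, all adjusted p = 1). At an unadjusted p under 0.05 there were 706, 384, 936 and 211 regions in these comparisons, where chance alone would give 1798. The DESeq2 test called 0, 1, 0 and 0 regions. The 95% confidence interval reached a median of 0.97 on the log2 scale to either side of the estimate in RA and 0.92 in Area X. In simulated data with 35937 regions and the fitted spread, 4% of 2-fold, 30% of 4-fold and 82% of 8-fold changes between singing and silent in RA were recovered; in Area X, with 35934 regions, these were 2%, 44% and 88%. In these simulations, changes of 4-fold or less within either nucleus were missed in most regions. Of unchanged simulated regions, 4.58% in RA and 4.47% in Area X had an unadjusted p under 0.05. The real counts of 706 and 384 lay well below the 1798 that chance would give. The real test thus behaved differently, and recovery in the real data may differ from these rates. For the mean of both nuclei, with 35937 simulated regions, 6% of 2-fold and 80% of 4-fold changes were recovered. The simulation drew the libraries of the nuclei independently. If both nuclei came from the same birds, these rates may be too high. For the difference of the singing effect, with 35938 simulated regions, 0% of 2-fold, 0% of 4-fold and 26% of 8-fold changes were recovered, so its 0 calls say less than those of the other comparisons. Fitted singing fold changes in RA and in Area X correlated across regions with r = 0.23, and differences of mean log2 CPM with r = 0.07. When behaviour labels were exchanged for the same library numbers in both nuclei, a test chosen after seeing the data, 24 of 35 labellings, the real one included, gave an r at least as high as 0.07 (range of the others -0.22 to 0.63, exact one-sided permutation p = 0.686).

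**Figure D4:**
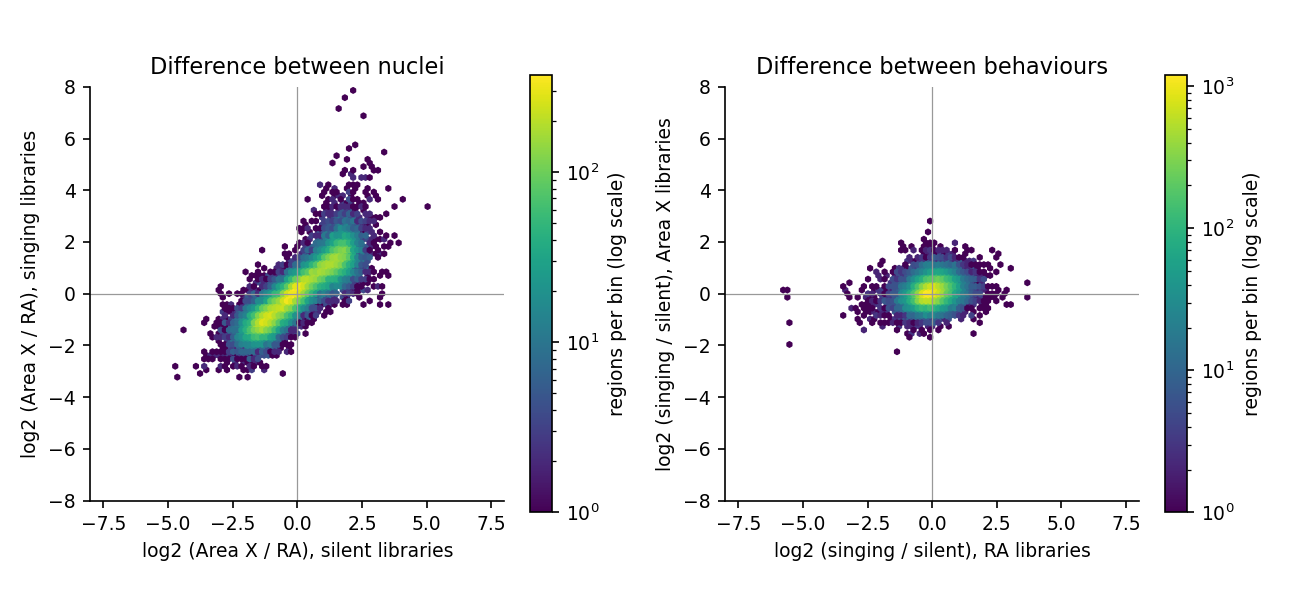
Fitted log2 fold changes of 35954 regions, as numbers of regions per bin on a log colour scale. Left, Area X over RA in silent (horizontal) and singing (vertical) libraries, r = 0.89; right, singing over silent in RA (horizontal) and Area X (vertical) libraries, r = 0.23.

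The regions with the smallest p are given as values that did not pass the threshold in the main edgeR fit. Some passed under settings added after seeing the data. In Area X, chr4:1194200-1195164 and chr28:4251820-4256192 passed with quality weights. With 2 surrogate variables, chr4:48331418-48331903 passed in RA, and chrUn:154099534-154099976 and chr14:5350477-5351847 in the mean of both nuclei. Those variables shrink the residual spread by construction. In Area X, chr4:1194200-1195164 had a CPM of 50.6 ± 5.48 in singing libraries (SD, n = 4) and 18.9 ± 4.82 in silent libraries (SD, n = 3), with a log2 fold change of 1.43 (95% interval 0.84 to 2.02). This was the region called by DESeq2. In RA its CPM was 23.4 ± 4.93 in singing and 22.1 ± 2.94 in silent libraries. At chr28:4251820-4256192 in Area X, CPM was 179 ± 64.0 in singing and 71.4 ± 0.93 in silent libraries, with an interval of 0.68 to 1.97. In RA, chr4:48331418-48331903 had 9.52 ± 4.64 CPM in singing and 0.681 ± 0.56 in silent libraries, with an interval of 1.91 to 5.58. In the mean of both nuclei, chrUn:154099534-154099976 had a log2 fold change of -1.97 (interval -2.82 to -1.11) and chr14:5350477-5351847 one of 1.08 (interval 0.59 to 1.57). For the difference of the singing effect between nuclei, chr4:1194200-1195164 had a log2 value of 1.42 (interval 0.58 to 2.25).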

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

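At chr3:39461302-39462622, 1 singing library stood apart from the others of its group. RA singing library 4 had 30.4 CPM there, while the other RA singing libraries had 9.93, 11.7 and 12.9, so its gap to the nearest was 0.856 of the whole range, above the 95% critical value of Dixon's test for 4 libraries. Among 110 groups of 4 tested in this way, 1 was picked out, and chance gives about 5.5. The silent groups, with fewer libraries, were not tested in this way. RA silent library 2 had 69.8 CPM at this region, against 13.9 and 7.83 in RA silent libraries 1 and 3. RA singing library 4 is the shallowest library, with 0.203 M (1e6) reads in regions. The region was called higher in Area X with every library left out in turn, with log2 fold changes from 2.33 to 3.36. It had been named for separated CPM in these same libraries, so this is no independent check.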

How the results depend on the processing

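The settings that leave out 3 libraries or the number 1 libraries, share the number across all 4 groups as a block, scale by signal or width, weight libraries, or add surrogate variables were added after seeing the data. For Area X against RA averaged over behaviour, 19316 regions were called, 11270 at an adjusted p under 0.01 and 9877 at or above the median CPM, where fewer were tested. The count ranged from 14130 to 20783 with 1 library left out, and 12844 regions were called with one sign in all 14 of those fits. Without RA silent library 2 and RA singing libraries 2 and 4, 18811 of the 19316 calls were shared, 97.4%, and none changed sign. The 20 named regions kept their direction and their side of the threshold in all 280 combinations with a library left out. They also did so in all 280 with another setting. They were named because they were called with separated CPM in these same libraries. Leaving 1 library out largely keeps that separation, so this is no independent check.

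In silent birds the count was 7135. It was 8 at an adjusted p under 0.01, 4080 with DESeq2 size factors in edgeR, 3920 at or above the median CPM and 0 in edgeR with the compared groups alone, where 15180 had an unadjusted p under 0.05. It was 16030 without the 3 libraries, 15243 with the shared number as a block, 22301 with quality weights, and 15461 and 19036 with 1 and 2 surrogate variables. With 1 library left out it ranged from 0 to 14521. In singing birds the count was 6635. It was 0 at an adjusted p under 0.01, 3936 at or above the median CPM, 10864 without the 3 libraries, 10685 with the shared number as a block and 10213 with 2 surrogate variables, and ranged from 0 to 9304 with 1 left out. Beyond the number of regions tested, the cause was not tested.

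Singing against silent gave 0 calls in each comparison with 1 library left out. With 2 surrogate variables, which shrink the residual spread by construction, 1 region passed in RA and 83 in the mean of both nuclei. In Area X, 1 passed in the DESeq2 test and 10 with quality weights. The other settings gave 0, and the cause was not tested. With 1 library left out, named calls were lost in 72 of 280 combinations in silent birds and 69 of 280 in singing birds; with other settings than thresholds, in 20 of 300 and 1 of 300. At an adjusted p under 0.01, 14 of 20 and 20 of 20 were lost. None reversed in these fits, but the naming rule asks for separated CPM, which makes a reversal unlikely.

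Library numbers did not pair all libraries. Deviations of the number 1 libraries correlated between nuclei at 0.59 in silent and 0.64 in singing birds, and between behaviours at 0.57 in RA and 0.58 in Area X. Those of the other numbers ranged from -0.19 to 0.46 between nuclei and from 0.05 to 0.22 in RA and 0 to 0.56 in Area X between behaviours. With the pool number within behaviour as a replicate block, 20645 regions were called averaged over behaviour, 15201 in silent birds, 11152 in singing birds and 0 for the difference of the singing effect. Toward Area X and RA, calls with this block numbered 9048 and 6153 in silent birds and 7267 and 3885 in singing birds. That block could not be fitted to comparisons of behaviour. Where a comparison uses all 4 groups, a fit to those groups alone changes nothing. The gene list settings and the whole-cell extract comparison were not run. Depth limits single values most in RA singing library 4, with a median of 3 reads per region.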

Other observations

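The tests of library position, of a library against the Area X libraries, of signal-dependent scaling, of the 3 RA libraries left out and of surrogate variables were chosen only after the result was seen.

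Other runs of neighbouring regions included chr26_random:1057065-1155250, 16 regions with a summed CPM of 3260 ± 738 in Area X and 1170 ± 572 in RA (SD, n = 7 each), and chr4:57982904-58054699, 16 regions with 1100 ± 403 and 298 ± 223. Toward RA, chr11:913796-988165 held 16 regions with 448 ± 160 in RA and 153 ± 30.1 in Area X, and chr7:36165696-36257170 held 16 with 646 ± 203 and 243 ± 50.9. Leaving out RA silent library 2 and RA singing libraries 2 and 4 gave chromosome 11 a share of 3.09% in RA and 2.27% in Area X (exact permutation p = 0.00303).

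RA silent library 2 correlated better with Area X than with RA libraries. Weaker enrichment is argued against, because its slope over regions that did not differ was 1.06, above the median of 0.99 of the other 13 libraries. An Area X library under an RA label stays open: the library exceeded all 7 Area X libraries in 46.3% of the regions called higher in RA without it, and RA singing library 4, whose label is also in doubt, in 36.3%. Area X libraries exceeded the other 6 in 2.28% to 34.5% (SD 12.1), and the bound set for that test, the highest plus the SD, was narrowly missed. The highest were the number 1 libraries of Area X, singing (34.5%) and silent (30.4%), and the rest reached at most 15.7%. At regions called higher in Area X without it, RA silent library 2 lay below all 7 in 33.3%. Area X libraries lay below the other 6 there in 1.6% to 60.2%. RA silent library 2 stood above every Area X library in the named runs chr10:16255984-16314220 (483 CPM against 102 to 215) and chrZ:14098145-14151673 (551 against 95.7 to 209), which were chosen with it counted as RA. Mixing of Area X material also stays open, with positions of 0.60 and 0.54 at regions higher in RA and in Area X but RA singing library 4 at 0.67, as does variation in dissection or between birds, untested.

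Wide regions were more often higher in Area X. A scaling difference that follows width is argued against as the whole cause. Regions up to 500 bp were higher in Area X 2.09 times as often within 2000 bp of a region over 4000 bp as over 20000 bp away from one (34.9% of 189 against 16.7% of 9849). Stronger enrichment in Area X libraries stays open, since mean slopes of 1.00 and 0.95 gave an exact permutation p of 0.672, and so does a difference that follows signal strength. Signal-dependent scaling left an excess of 5.6 percentage points toward Area X in regions over 4000 bp, but it would also remove a biological difference that follows signal, and a difference between the nuclei stays open, untested.

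No region passed between singing and silent in the main edgeR fit. In Area X, the DESeq2 test called 1 region and quality weights 10. Spread from RA silent library 2 and RA singing libraries 2 and 4 stays open: 0 regions passed in RA when they were left out, with 1687 at an unadjusted p under 0.05, but 2 libraries per behaviour then remained. Low power for 2-fold changes may contribute, since 4% of simulated 2-fold changes in RA were recovered. Shared variation between libraries stays open. With 2 surrogate variables 83 regions passed in the mean of both nuclei, 76 of them higher in singing, between the bounds of 0 and 100 set for that test. The variables were taken from the residuals of the same model and shrink its spread by construction, so these calls cannot decide the question. An absence of changes stays open too.

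Other groupings of the libraries were tested for each count. For Area X against RA averaged over behaviour, only the real one of 100 groupings drawn within behaviour gave as many as 19316 calls. A share of 1 in 100 is the smallest these draws can give. The highest other gave 16431. That grouping exchanged RA silent library 2 and RA singing library 4 with the number 1 libraries of Area X, silent and singing, which are the 4 libraries nearest to one another on the axis between the nuclei. For silent birds, 1 of 10 groupings gave 7135 and the highest other 0, and 10 groupings are too few for a share under 0.05. For singing birds, 1 of 35 gave 6635 and the highest other 5421. This share is the smallest possible and the count depended on single libraries, so chance is not excluded. For singing against silent the real counts were 0, so 35 of 35 groupings in RA, 35 of 35 in Area X, and 100 of 100 for the mean and for the difference gave as many calls. The highest others were 3963, 0, 7398 and 3942. In RA the grouping with 3963 calls exchanged RA silent library 2 with RA singing library 1. Any call came from 4 of the other groupings in RA, 0 in Area X, 5 for the mean and 8 for the difference. Such counts, against 0 for the real grouping, may point to a structure among the libraries other than behaviour, which these groupings did not show in Area X alone. Correlations there did not follow behaviour throughout. Area X singing library 1 had a Spearman coefficient of 0.951 with Area X silent library 1, but 0.796 and 0.827 with Area X singing libraries 3 and 4.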
